A study of Mus musculus with 2 samples.

How the data were processed

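The measured material was the medial ganglionic eminence (MGE), the embryonic ventral forebrain region that makes cortical interneurons and the neurons of the basal forebrain and pallidum. Tissue came from CD-1 mouse embryos at embryonic stage E11.5 and was profiled on the 10x Chromium platform with MULTI-seq, in which lipid-anchored sample barcodes let several cell suspensions share 1 run. Per the labels, the 2 deposited samples are the RNA library and the sample barcode library of 1 pool. The deposited barcode list named 6 sample barcodes. Of these, 4 marked GFP-gated cells, 2 for each of the enhancers hs192 and hs799, and 2 marked ungated cells, 1 for each enhancer.

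Per the submitters' processing notes, bcl2fastq and Cell Ranger 3.0.2 were used with the mouse build GRCm38. The deposited matrix held 18088 genes and 4001 cells as whole numbers from 0 to 1245, of which 22.1% were above 0. Its unit was treated as a score made by the authors from UMI counts, because the deposited values were not raw counts. Cell totals lay between 10475 and 14196, with a median of 12506. Over 851 genes of mean near 1 and little spread, the share of values equal to 1 ranged from 0% to 59.2% between cells, with a median of 34.4%. In 209 cells, 5.22% of all, that share was under 10%. Scaling to a common depth followed by rounding produces such gaps. The step that made them is not given in the sources used here, and raw sequencing depth per cell is therefore unknown. The table had 0 mitochondrial rows, and its rarest gene had a value in 10 cells. Of the gene identifiers, 18071 were found in the GENCODE annotation of GRCm38, 17983 of them with the same symbol. On 9 symbols that named more than 1 row, the row with the largest sum kept the symbol.

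No map from cells to sample barcodes was used here, so the matrix was treated as 1 sample. The comparison of the enhancer lines and the comparison of cells with and without a reporter transcript were not made. Cells are not replicates, and no p-value, standard error or count of changed genes was computed. The design fixed before the data were examined had assumed UMI counts and planned Poisson and ratio intervals. Those were dropped because the values were not counts.

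Filters of at least 1000 genes per cell and at most 10% mitochondrial values removed 0 cells, the latter because no mitochondrial gene was present. Scrublet, run in scanpy 1.11.5 at an expected doublet rate of 5%, called 6 cells (0.150%), which were removed and left 3995. So few calls on depth-corrected values do not show that doublets were rare. Values were scaled to 10000 per cell and log-transformed. The 2000 most variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1 (igraph 0.11.9, seed 0, run to convergence) gave 18 clusters. Clusters were named from 16 marker lists fixed before the data were examined, with 100 of 139 markers measured. A gene counts as measured if the matrix held a row for it. Whether a gene without a row was absent from the cells or left out as rare is not given in the sources used here. Microglia had 1 measured marker, choroid plexus 1 and mural cells 2, so these types could not be named. A name needed at least 3 markers at 1.5 times the level of all other cells and in at least 10% of cells. The class with the highest mean standardized level was taken, and a cluster stayed unnamed where its 10 leading genes by ratio held more markers of another class. A tie went to the class whose marker stood first.

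The scoring rule and the number of Leiden iterations were set after cluster values had been seen. Altogether 3 versions of the tie rule were run (the name kept, the name lost, and the version used), and Leiden clustering was run both with 2 iterations and to convergence. The version used differs from the first in leaving unnamed 1 cluster led by Otp, and from the second in naming 1 subventricular zone cluster. All versions are among the alternatives.

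A gene's level in a class is its summed value per 10000 summed values of that class, given with the standard deviation (SD) over cells, which describes the spread of cells in 1 library. A ratio is the ratio of 2 levels. Shares of cells carry exact (Clopper-Pearson) 95% binomial intervals, which cover the counting of cells only. For co-detection each cell was thinned to 10000 values, which left out no cell. Deposited totals already lay in a narrow range, so thinning changed little and did not equalize raw sequencing depth. Named genes comprised members of the 18 fixed gene lists and, outside them, the 12 genes at each end of a ranking among genes with at least 30 summed values, without ribosomal protein genes and unnamed gene models. The ranking used the bound nearest to 1 of an interval computed as if summed values were counts. It ordered genes only, and no such interval is reported. A list is summarized by the median log2 ratio of its members with at least 30 summed values, where a gene with no value in a class took a floor of 3 summed values.

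The ratio step was tested on simulated data in which genes were changed by known ratios. The simulated values were Poisson counts drawn from a shared profile, with no spread between cells beyond counting and depth, and no rounding. Recovery therefore checks the calculation and does not give the error of ratios in the deposited values, which were not counts. For the lineage comparison, with 11051 genes run, 98.0% of genes raised 2-fold and 96.0% of genes raised 4-fold came back within 1.5 times of the true ratio, as did 93.8% and 91.3% of genes lowered to a ratio of 0.5 and 0.25. For neurons against progenitors, with 13858 genes run, these shares were 92.0%, 100%, 93.9% and 95.9%. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Alternatives fixed beforehand changed the cell filter, doublet removal, resolution, the number of variable genes and the use of cell cycle genes. They also changed the scaling, the gene minimum, the log scale and the detection threshold. Another split the values at random so that classes and levels came from separate values. Because the values were not counts, both parts of this split can stay correlated, so levels need not be independent of the classes. Leaving out the 209 cells described above, the unscaled mean per cell, the 2 Leiden iterations and the tie rules were added after the data were seen.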

Results

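A single pooled library of cells from the E11.5 mouse MGE was profiled by single-cell RNA sequencing. The pool combined embryos carrying 1 of the 2 enhancers hs192 and hs799, and 4 of its 6 sample barcodes marked GFP-gated cells. The gate can therefore set the share of any class. The matrix held 4001 cells with 2471 to 5486 genes per cell (median 3989). There were no replicate libraries, so no difference reported here could be set against a spread between animals. The series title names the GABAergic and cholinergic lineages, and the comparisons made were of cell classes within the pool.

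Progenitors and neurons of the MGE made up most of the cells. Ventricular zone progenitor-like cells accounted for 27.2% of the 3995 cells used (95% interval 25.8% to 28.6%) and subventricular zone progenitor-like cells for 15.3% (14.2% to 16.5%). GABAergic MGE neuron-like cells made up 11.4% (10.4% to 12.4%), cholinergic neuron-like cells 11.1% (10.2% to 12.1%) and neuron-like cells of the neighbouring lateral ganglionic eminence (LGE) 5.93% (5.22% to 6.71%). A further 29.1% (27.7% to 30.5%) stayed unnamed. The neuronal shares depended on the settings. Over 13 settings, the GABAergic share ranged from 11.4% to 27.4% and the cholinergic share from 11.1% to 23.0%. The ventricular zone share ranged from 24.8% to 27.5%. Class shares were not computed where classes and levels came from separate values, or where Otp, Hmx2 and Hmx3 were left out of the clustering. The GABAergic and cholinergic shares given here were the lowest of those ranges.

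**Figure D1:**
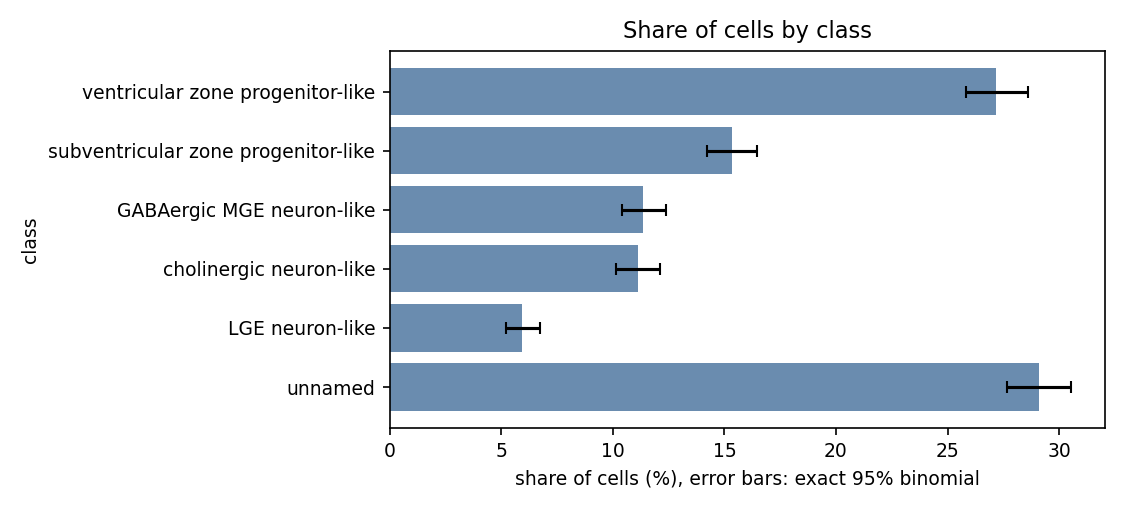
Share of the 3995 cells in each class (horizontal axis, percent), with exact 95% binomial intervals that cover the counting of cells only. Ventricular zone progenitor-like and unnamed cells were the 2 largest groups, at 27.2% and 29.1%.

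Clusters of the ventricular zone class shared Hes5, a Notch effector, and 3 of the 4 were led by cell cycle genes. Hes5 stood at 12.2 per 10000 in the ventricular zone class (SD 9.26) and Olig2 at 2.43. Cluster 2 was led by replication-dependent histone genes such as Hist1h1b, cluster 4 by Ung, Cdc6 and Mcm3 of S phase, and cluster 7 by Cdc20, Cenpf and Ccnb1 of mitosis. Cluster 18, with 89 cells, was led by other genes, among them Igfbp5, Fst and Wnt7b. The subventricular zone class had the highest class level of the Notch ligand Dll1 (0.958 against 0.359 in the ventricular zone class). In the LGE class, Ebf1 reached 12.6, Meis2 10.0 and Isl1 8.22, and Tac1, which encodes substance P, reached 2.40. Hes5, Dll1, Ebf1 and Meis2 also served to name these classes, so their levels are not independent of the naming.

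Most unnamed cells carried enough GABAergic markers for a name but lost it through the leading genes of their clusters. These held markers of the cholinergic class in clusters 3 and 12. In cluster 5 they held a marker of neurons of the caudal ganglionic eminence (CGE), and in cluster 13 one of LGE neurons. Clusters 3, 5, 12 and 13 held 956 cells or 23.9% of the total. In clusters 3 and 12 the level of Lhx8, a LIM-homeodomain factor of the cholinergic lineage, was 11.4 in both, beside 10.3 in the cholinergic class. Cluster 3 was led by Gbx1 (1.66) and Nr4a2 (0.966), and cluster 12 by Kitl (2.11) with Zic1 at 6.75. Cluster 5 was led by St18 (2.54), and cluster 13 by Gabra2 (1.04), which encodes a GABA-A receptor subunit. Over the same 13 settings, the unnamed share ranged from 7.33% to 35.2%.

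**Figure D2:**
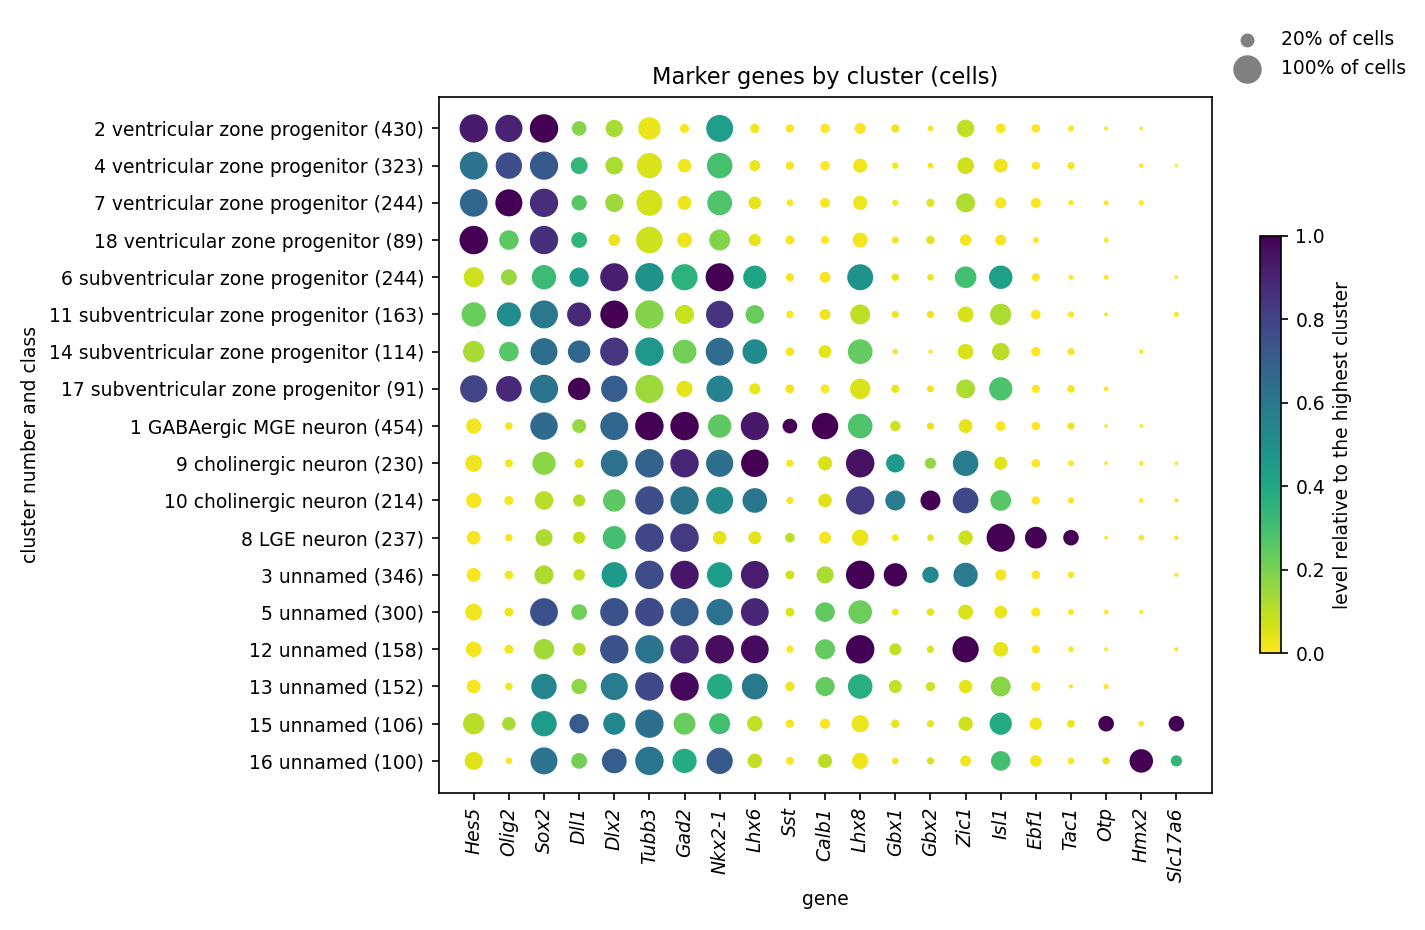
Marker levels in the 18 clusters. Rows are clusters with their class and number of cells, columns are genes, point size is the percent of cells with a value, and colour is the level relative to the highest cluster of that gene. Lhx8 and Zic1 are high in the cholinergic clusters 9 and 10 and also in the unnamed clusters 3 and 12, and Sst is highest in cluster 1.

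The lineage question was addressed by comparing the 444 cholinergic neuron-like with the 454 GABAergic MGE neuron-like cells. Unnamed clusters 3 (346 cells) and 12 (158 cells), which carried markers of both lineages, were left out, as were clusters 5 and 13. The ratios therefore do not cover those cells. Of the cholinergic class, 230 cells belonged to cluster 9, which was named from 3 elevated cholinergic markers, the fewest the rule allows. Both classes expressed Lhx6, the MGE LIM-homeodomain factor of the interneuron lineage (chromosome 2, 36081953 to 36105408, GRCm38, protein-coding), at nearly the same level, 2.98 (SD 2.53) and 3.45 (SD 2.05). Lhx8 (chromosome 3, 154306294 to 154330659) was 3.20-fold higher in the cholinergic class, at 10.3 (SD 4.82) against 3.21 (SD 3.66). The interneuron neuropeptide gene Sst (chromosome 16, 23889573 to 23890958) was 99.1-fold higher in the GABAergic class, at 3.34 (SD 11.1) against 0.0337, with a value in 22.9% of GABAergic cells. Lhx8, Sst and the other class markers also served to name the clusters, so their difference is not independent of the classes.

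Transcription factors of the cholinergic lineage were higher in the cholinergic class as a group. All 9 list members could be measured, with a median log2 ratio of 4.01. Of these, 6 were also class markers, so the list's difference is not independent of the naming. At resolution 0.5 the list's median was 2.98. Zic1, a zinc finger factor of the septum and ventral forebrain, was at 4.58 (SD 4.26) against 0.270, Isl1 at 1.27 against 0.0841, and Gbx2 at 0.578 against 0.0358. Nkx2-1, which specifies the MGE, was 2.36-fold higher. The single member of the cholinergic synthesis list with enough summed values was Ache, acetylcholinesterase, at 0.0692 against 0.00716. Chat and Slc18a3 encode the acetylcholine-synthesizing enzyme and the vesicular acetylcholine transporter. Both were fixed as markers but had no row in the matrix, so the cholinergic class was named without them. The rarest gene with a row had a value in 10 cells, so a missing row does not show that a gene was not sequenced. Both genes may have been found in too few cells to be kept, which cannot be told here.

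Genes of interneuron migration and maturation were higher in the GABAergic class. Over the 18 members with at least 30 summed values the median log2 ratio of cholinergic to GABAergic levels was -1.69, and -0.88 over the 9 members that were not class markers. The transcription factor gene Maf gave a log2 ratio of -4.20, the neuregulin receptor gene Erbb4 -2.98, the neurexin ligand gene Nxph1 -3.38 and Npy -3.84. Nrp1, a semaphorin receptor gene, lay on the other side at 1.38. Under 7 other settings the list's median lay between -0.58 and -1.0.

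GABA synthesis and transport genes differed little between the classes. Their median log2 ratio was -0.40, and it was 0.051 with 4000 variable genes. Gad2, a GABA-synthesizing enzyme gene, was at 6.33 in the cholinergic class (SD 3.45) and 8.37 in the GABAergic class (SD 3.64). The Dlx family of forebrain GABAergic homeobox genes had a median of -0.68, although Dlx6 itself was at 1.14. Pan-neuronal genes had a median of -0.07.

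Signalling and guidance genes differed in both directions. Of the 10 measured Shh pathway members, 5 had at least 30 summed values, with a median of 1.41, and Shh itself was 4.56-fold higher in the cholinergic class, at 1.11 (SD 1.23) against 0.243. That list's median was 0.52 with a minimum of 100 summed values. Axon guidance genes had a median of 0.02, which turned to -0.011 without rescaling and was 0.70 at resolution 2, over a range from Epha5 at -3.18 to Sema3c at 1.85. The dissociation stress list had a median of -1.09 and was led by the immediate early gene Fos at -1.98; this was -0.23 for the list at resolution 0.5. Other medians were 0.19 for MGE regional factors, 0.68 for LGE and CGE regional factors, -0.24 for the Notch pathway, -0.64 for the Wnt and Fgf pathway, 0.10 for S phase, 0.42 for G2 and M phase, 0.18 for hypoxia and glycolysis, 0.11 for hemoglobin transcripts and -0.08 for female and male transcripts.

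Outside the lists, the ranking put Tspan18, Robo3, Grin3a, Aifm3, Fgd5, Chl1, Palmd, Vstm2l, Zfhx3, Pou3f1, Abca4 and Id4 at the cholinergic end. Among them, the POU factor gene Pou3f1 was at 6.69 (SD 7.19) against 0.702, the zinc finger homeobox gene Zfhx3 at 6.51 against 0.625, and Robo3, a Slit receptor family gene, at 0.825 against 0.034. Tspan18, Grin3a and Abca4 were listed at 0 in the GABAergic class. The GABAergic end held Efcab6, Calb1, Tmem132b, Cxcl14, Ptcra, Npas1, Tox2, Syt6, Neb, Man2a1, Tent5a and Smoc1. Calb1, the calcium-binding protein calbindin, was 18.8-fold higher there, at 8.35 (SD 9.0) against 0.445. Tmem132b and Ptcra were listed at 0 in the cholinergic class, and Ptcra had a value in 0.441% of GABAergic cells. Several of these ratios depended on the settings. When classes and levels came from separate values, the log2 ratio of Id4 turned from 3.28 to -0.66. That of Zfhx3 was then 0.42 in place of 3.38, Fgd5 0.25 in place of 4.44, Cxcl14 -0.11 in place of -5.54 and Calb1 -1.82 in place of -4.23. With 4000 variable genes Vstm2l was at 0.084 in place of 3.78 and Pou3f1 at 1.56 in place of 3.25, and at resolution 0.5 Robo3 was at 2.71 in place of 4.6. With a minimum of 100 summed values, 8 of the 12 genes at each end were shared, and 6 of 12 at the cholinergic end and 8 of 12 at the GABAergic end when ordered by the ratio itself. In the cholinergic class 11.9% of cells belonged to those that skip the value 1, against 3.74% in the GABAergic class.

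Neurons were compared with progenitors to describe the step from the ventricular zone to the mantle. The 898 GABAergic and cholinergic neuron-like cells together were set against the 1086 ventricular zone progenitor-like cells. Pan-neuronal genes had a median log2 ratio of 3.76 over 12 members, with the neuronal tubulin gene Tubb3 at 35.3 (SD 11.8) against 2.10 and the microtubule regulator gene Stmn2 34.7-fold higher. GABA synthesis genes had a median of 5.21, with Gad2 at 7.37 against 0.152. The Dlx family had a median of 4.11 and interneuron genes 3.55. Over members that were not class markers, the median was 1.13 for 10 interneuron genes and 2.67 for 2 GABA synthesis genes. Nkx2-1 was similar in both, at 2.37 (SD 2.35) and 1.96 (SD 1.82).

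Proliferation and Notch genes were higher in the progenitors. S phase genes had a median log2 ratio of neurons to progenitors of -4.30 over 20 members and G2 and M phase genes -5.73 over 24. The Notch pathway median was -4.88, with its effector genes Hes1 at -7.06 and Hes5 at -5.53, while Rbpj, the DNA-binding partner of Notch, was at 0.88. Hes1 and Hes5 also served to name the ventricular zone class. Over the 7 Notch pathway members that were not class markers, the median was -4.97. Shh pathway genes had a median of -3.38, including the target genes Gli1 at -6.13 and Ptch1 at -1.86, whereas Shh was at 1.55. This median was -2.51 with a minimum of 100 summed values. Hypoxia and glycolysis genes had a median of -1.41, and Ldha, lactate dehydrogenase, was at 0.471 against 7.41.

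Regional and guidance genes were mixed. The axon guidance median was 1.35, from Robo2 at 4.75 to Ntn1 at -3.87, and was 2.66 with a minimum of 100 summed values. Other medians were 0.58 for MGE regional factors, -1.12 for LGE and CGE regional factors, 2.29 for cholinergic lineage factors, 3.08 for the 2 cholinergic synthesis genes with at least 30 summed values, -1.01 for the Wnt and Fgf pathway, 0.84 for dissociation stress, 0.08 for hemoglobin transcripts and 0.28 for female and male transcripts. Outside the lists the neuronal end held Calb1, Nrxn3, Ripor2, Runx1t1, Actl6b, Arl4d, Carlr, Scrt1, Cbfa2t3, Rmst, Myt1 and AI606473. The presynaptic adhesion gene Nrxn3 was 43.9-fold higher, at 5.89 (SD 2.79) against 0.134. The progenitor end held Esco2, Prc1, Exo1, Clspn, Hist1h1b, Nfix, Sox8, Bub1b, Ptx3, Sparc, E2f8 and Hmmr, several of them genes of DNA replication or mitosis. Carlr was listed at 0 in the progenitors and Sox8 at 0 in the neurons. With a minimum of 100 summed values, 11 of 12 neuronal and 12 of 12 progenitor genes were shared, and 7 and 4 of 12 when ordered by the ratio itself. Sparc, a matrix glycoprotein gene, was at 3.05 (SD 2.59) in progenitors and 0.0403 in neurons. Median cell totals were 11944 in neurons and 13511 in progenitors, and levels not rescaled shifted all log2 ratios by -0.12. Neuronal and cell cycle genes also separated the clusters, so their difference is not independent of the classes.

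Lhx6 and Lhx8 were detected together in most MGE neuron-like cells. After thinning, 83.8% of the 790 cells with an Lhx6 value also had Lhx8 (81.0% to 86.3%), and 88.0% of the 108 cells without Lhx6 did (80.3% to 93.4%). Isl1 (chromosome 13, 116298281 to 116309689) was found in 13.9% of cells with Lhx6 (11.6% to 16.5%) and in 61.1% of cells without it (51.3% to 70.3%). Zic1 was found in 42.7% of cells with Lhx6 (39.2% to 46.2%) and 73.1% without (63.8% to 81.2%). Gbx2 shares were 14.4% and 11.1%, and Nkx2-1 shares 75.1% and 74.1%, with overlapping intervals. These pooled shares mix the classes, since 84 of the 108 cells without Lhx6 were of the cholinergic class. Lhx8, Isl1, Gbx2 and Zic1 were also cholinergic markers and Lhx6 a GABAergic marker, so their pooled shares are not independent of the naming.

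Shares by Lhx6 were also compared within the classes. Lhx8 was found in 70.5% of the 430 GABAergic cells with Lhx6 (65.9% to 74.7%) and 54.2% of the 24 without (32.8% to 74.4%), and in 99.7% and 97.6% of cholinergic cells, with overlapping intervals in both classes. Zic1 was found in 74.7% of cholinergic cells with Lhx6 (69.9% to 79.1%) and 88.1% without (79.2% to 94.1%), where the intervals overlapped without thinning, and in 15.8% and 20.8% of GABAergic cells, with overlapping intervals. Isl1 was found in 22.2% of the 360 cholinergic cells with Lhx6 (18.0% to 26.9%) and 76.2% of the 84 without (65.7% to 84.8%). The cholinergic class joins clusters that differ in both genes. In cluster 10 alone Isl1 was found in 32.0% of 150 cells with Lhx6 (24.6% to 40.1%) and 89.1% of 64 without (78.8% to 95.5%), and in cluster 9 in 15.2% of 210 (10.7% to 20.8%) and 35.0% of 20 (15.4% to 59.2%), with overlapping intervals. In cluster 10 Gbx2 was found in 52.7% of cells with Lhx6 (44.4% to 60.9%) and 17.2% without (8.90% to 28.7%), and Zic1 in 73.3% (65.5% to 80.2%) and 92.2% (82.7% to 97.4%), with intervals that stayed apart without thinning. In cluster 9 the intervals of Gbx2 and Zic1 overlapped. In GABAergic cells the Isl1 shares were 6.98% (4.76% to 9.81%) and 8.33% (1.03% to 27.0%), so no difference was detectable there. Over the whole cholinergic class Gbx2 was found in 27.8% of cells with Lhx6 and 14.3% without, with overlapping intervals, and Nkx2-1 in 63.0% and 37.5% of GABAergic cells and 89.4% and 84.5% of cholinergic cells.

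As background, LGE neuron-like cells had an Lhx8 value in 24.9% (19.5% to 30.9%), Gbx2 in 2.53% and Zic1 in 18.1%. For Isl1, which 98.3% of LGE neuron-like cells carried, the background was taken from ventricular zone progenitor-like cells, at 10.3% (8.57% to 12.3%). The interval of the 13.9% in MGE neurons with Lhx6 overlapped it. Such an overlap does not show equal shares, and this pooled share mixes the classes. In cholinergic cells with Lhx6 the Isl1 share was 22.2% (18.0% to 26.9%), with an interval above that of the background. Cluster 10 was at 32.0% (24.6% to 40.1%), also above it, and cluster 9 at 15.2% (10.7% to 20.8%), with an overlapping interval. The Isl1 share of 6.98% (4.76% to 9.81%) in GABAergic cells with Lhx6 was not above its background, with overlapping intervals. The same held for the Zic1 share of 15.8% (12.5% to 19.6%), beside 18.1% (13.5% to 23.7%) in LGE neuron-like cells. Ventricular zone progenitor-like cells had Zic1 in 27.4%. Whether the cells used as background transcribe these genes themselves was not tested. Median totals were 12967 in LGE neuron-like cells, 13511 in ventricular zone progenitor-like cells and 11944 in the MGE neurons. Without thinning, Lhx8 was found in 85.3% of Lhx6-positive MGE neurons and Isl1 in 15.6%. With 4000 variable genes, the Isl1 share in MGE neurons without Lhx6 was 29.2%. With a minimum of 2 values, Isl1 was found in 5.36% of MGE neurons with Lhx6 and 34.5% of those without.

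**Figure D3:**
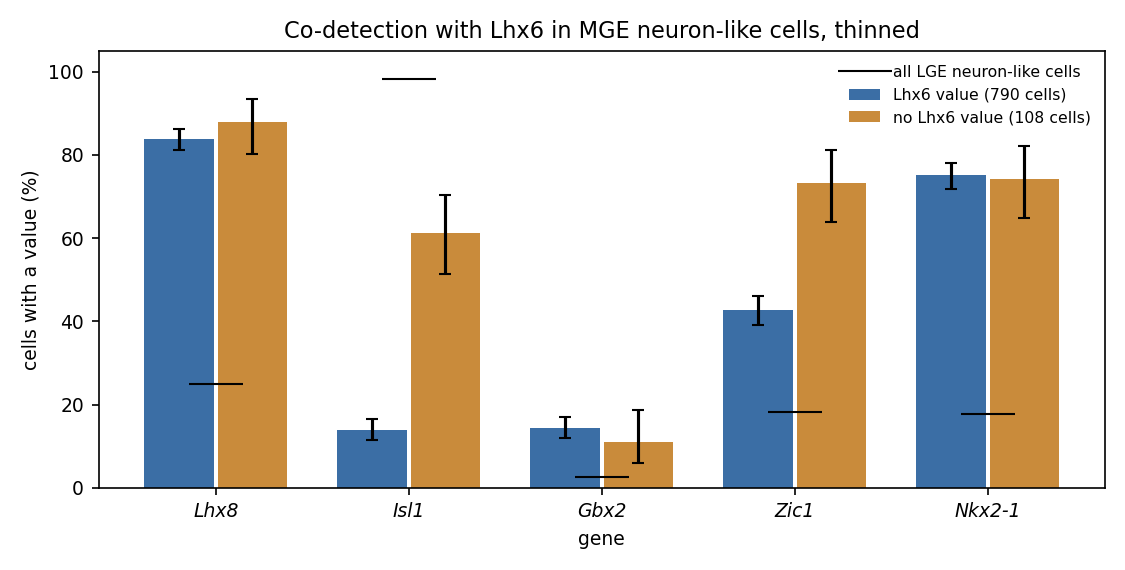
Percent of MGE neuron-like cells with a value of each gene (vertical axis), split by Lhx6 in cells thinned to 10000 values, with exact 95% binomial intervals and black marks for all LGE neuron-like cells. Isl1 stands at 13.9% with Lhx6 and 61.1% without, in a pool where 84 of the 108 cells without Lhx6 were cholinergic neuron-like.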

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

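Leaving out the cells that skip the value 1, the 2 Leiden iterations, both other tie rules and the unscaled mean per cell were chosen only after the data were seen. Shares of the neuronal classes moved under several settings, while the ventricular zone share of 27.2% lay within 24.8% to 27.5% over 13 settings. Using all cells as filtered and a minimum of 2000 genes removed no cell, so these settings say nothing about stability. The difference of mean log values, compared by sign only, kept the sign of all 62 results. Alternatives for the enhancer lines and the reporter transcript were not run, since neither comparison was made. The cause was not tested for any value that follows, except that a higher minimum leaves fewer genes or cells.

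With doublet calls kept, the GABAergic share was 14.4%, cholinergic 22.0%, LGE 3.82% and unnamed 15.1%. Lhx8 was in 89.2% of MGE neurons with Lhx6, and the interneuron list's median log2 ratio was -1.0. At resolution 0.5 the GABAergic share was 27.4%, cholinergic 17.6% and unnamed 7.33%, with medians of 2.98 for cholinergic lineage factors, -0.59 for interneuron genes and -0.23 for dissociation stress. At resolution 2 the subventricular zone share was 13.5%, GABAergic 18.9%, cholinergic 19.4% and unnamed 15.7%, with -0.95 for interneuron genes and 0.70 for axon guidance.

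With 1000 variable genes the subventricular zone share was 20.7%, GABAergic 16.3%, cholinergic 14.7% and unnamed 16.05%, with 0.68 for axon guidance. With 4000 the GABAergic share was 19.6%, cholinergic 17.8% and unnamed 11.6%, and Isl1 was in 29.2% of MGE neurons without Lhx6. The medians were then 3.09 for cholinergic lineage factors, -0.71 for interneuron genes, -0.31 for dissociation stress and 0.051, a reversed sign, for GABA synthesis. Without cell cycle genes the ventricular zone share was 24.8%, subventricular zone 11.4%, GABAergic 20.6%, cholinergic 23.0% and unnamed 9.26%. Isl1 was in 50.9% of MGE neurons without Lhx6, and the interneuron median was -0.87.

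Without the cells that skip 1 the subventricular zone share was 11.6%, GABAergic 13.0%, cholinergic 16.1%, LGE 3.17% and unnamed 25.8%, and axon guidance was at 1.95 for neurons over progenitors. With 2 Leiden iterations the subventricular zone share was 13.3%, GABAergic 19.3%, cholinergic 13.7% and unnamed 20.5%. Lhx8 was then in 80.4% of MGE neurons with Lhx6, and medians were -0.74 for interneuron genes, 0.66 for axon guidance and -0.46 for dissociation stress. Where ties kept the name, 26.4% of cells were unnamed. Where ties lost it, 35.2% were unnamed and the subventricular zone share was 9.21%.

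With a minimum of 2 values, Lhx8 was in 75.0% of MGE neurons with Lhx6 and 75.7% without, and Isl1 in 5.36% and 34.5%. With classes and levels from separate values, cholinergic lineage factors were at 3.32, interneuron genes at -0.58, the Shh pathway at 0.70 between lineages and -2.53 for neurons over progenitors, and Id4 reversed to -0.66. With a minimum of 100 summed values the Shh pathway was at 0.52 and -2.51, and axon guidance at 2.66 for neurons over progenitors. Without rescaling, axon guidance between lineages reversed to -0.011. Among named genes, 142 values of the lineage comparison moved by over 1.5 times without a change of sign, 1 reversed and 265 counted as the same. In the comparison with progenitors 37 moved in this way and 371 counted as the same. Those counted as the same include settings that removed no cell and the difference of mean log values, compared by sign only. Raw depth is unknown, so its limit on rare transcripts could not be given.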

Other observations

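The tests of free RNA, for Otp, Hmx2 and Hmx3 and for Lhx8, were chosen only after the result was seen. A pair of unnamed clusters carried transcription factors of neurons not named in the series. Cluster 15, with 106 cells, was defined by Otp (2.61 per 10000), Nhlh2 (2.19), Neurod1 (1.03) and Sim1 (0.961), and by Slc17a6 (0.674), which encodes a vesicular glutamate transporter. Its Gad2 level was 1.94, beside 7.48 in the cholinergic cluster 9. Otp had a value in 26.4% of its cells, so the cluster was mixed. Cluster 16, with 100 cells, was defined by the homeobox genes Hmx2 (3.38) and Hmx3 (2.83) and by Lhx5 (1.41), with Nkx2-1 at 4.15. Cluster 18, with 89 progenitor-like cells, was defined by Igfbp5 (8.45), Fst (2.28), Wnt7b (1.6), Pax6 (0.60) and Fezf2 (0.582).

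The cholinergic class joined clusters of different profile. Cluster 9 held more Arl4d (2.39 against 0.25), Lhx6 (3.69 against 2.24) and Gad2 (7.48 against 5.15) than cluster 10. Cluster 10 held more Isl1 (2.18 against 0.384), Gbx2 (1.0 against 0.166), Zic4 (1.79 against 0.362) and Foxp2 (1.99 against 0.321). Both expressed Shh, at 1.2 in cluster 9 and 1.02 in cluster 10. In cluster 9, 17.8% of cells skip the value 1, against 5.61% in cluster 10. Cluster 9 was named cholinergic from 3 elevated markers, the fewest the rule allows. Its Lhx6 level of 3.69 lay beside 3.45 in the GABAergic class. After thinning, its cells had Lhx8 in 99.6% and Zic1 in 75.7%, but Isl1 in 17.0% and Gbx2 in 9.57%. Genes that define a cluster are its description and no independent result.

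Clusters 15 and 16 held 206 cells or 5.16% of all, and free RNA could give such a signal. Since Otp, Hmx2 and Hmx3 lead these clusters, cells were also clustered without the 3 genes, and the clusters with the highest shares then held 137 of the 206 cells. A value of any of these genes was found in 68.3% of the 139 cells of those clusters and in 1.82% of all others, a ratio of 2.66%. Free RNA would give like shares, so this argues against it for those cells and leaves it open for the rest. Whether these cells belong to the MGE or to tissue beside it stays open.

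Lhx6 and Lhx8 were found together in 693 GABAergic and cholinergic neuron-like cells, and doublets or free RNA could produce this. Female and male transcripts occurred together in 1.15% of those cells (0.50% to 2.26%), below the 10% set for doublets as the source. The Lhx8 share in LGE neuron-like cells, without thinning, was 34.6% of that in Lhx6-positive MGE neurons. Lhx8 helped to name the cholinergic cells of that pool, so the pooled share is not independent of the naming. Among only the GABAergic cells with Lhx6, Lhx8 was found in 73.3% without thinning (68.9% to 77.4%). In LGE neuron-like cells this was 29.5% (23.8% to 35.8%), so free RNA alone does not give the observed share in GABAergic cells. One hypothesis is that both genes are transcribed in the same cells at this stage, which was tested on the same data that raised it. Doublets of cells of the same sex cannot be seen this way.

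The female share of cells with a clear sex differed between clusters, from 51.2% in cluster 14 (39.8% to 62.6%) to 82.0% in cluster 12 (74.3% to 88.3%). Differences in depth or Xist level might produce this without a difference in sex. Over the clusters, the share of cells with Y transcripts fell as the share with Xist rose, with a Pearson r of -0.91, which argues against that explanation. Uneven pooling of embryos by gate or line and a difference between the sexes cannot be told apart, since 0 cells could be assigned to a sample barcode.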
